A study of Mus musculus with 11 samples.

How the data were processed

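RNA was measured in the last 2 cm of the small intestine, the distal ileum, of mice that had received dextran sodium sulfate, a polysaccharide given to mice to injure the intestinal lining. There were 11 libraries, 6 from WT mice and 5 from dIEC mice. Per the labels, mice of both groups carried floxed alleles of H2-Ab1, the gene of the beta chain of the MHC class II molecule I-A, and dIEC mice also carried the Villin:Cre transgene, whose Cre recombinase is made in intestinal epithelial cells. The design text gives the mice as 6 and 5, so each library was taken as 1 mouse. That text writes the Cre-negative genotype for both groups, and the groups used here follow the genotype label of each sample. Replicates carry the library number of their title, and no number occurs in both groups. The p-values measure the spread between these libraries, and cage, litter and batch are not given in the sources used here.

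Per the labels' protocols, RNA was extracted from Trizol with a Zymo Direct-zol kit, and libraries were made with the directional NEBNext Ultra kit. The molecule is given as total RNA. Per the submitters' processing notes, reads were aligned with TopHat2 and the genome build was mm10. The counting tool, its strand setting, the annotation and the treatment of reads with several positions are not given in the sources used here. The authors deposited a single table of whole-number counts per gene with no normalization, as the values themselves show. All 11 of its value columns matched a sample by name.

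The table had 31169 rows, of which 1 named no gene. That row held 0.00778 to 0.0147% of the counts of a library and was left out of the library sizes and the tests. Of the remaining symbols, 99.2% occur in the GENCODE vM21 annotation of the same genome build (GRCm38), from which coordinates and gene types were taken. Total counts ran from 6603965 to 9681698 per library. Much of this was ribosomal. Rows of ribosomal RNA type together with Gm42418, a long non-coding locus that overlaps the ribosomal RNA copy CT010467.1 on chromosome 17, took 34.6 ± 6.91% of the counts in WT (SD, n = 6) and 40.5 ± 8.50% in dIEC (n = 5; two-sided exact permutation p = 0.216). Protein-coding genes other than Lars2, a gene of a mitochondrial tRNA synthetase that held 3.11 to 5.31% of the counts, kept 1510296 counts in dIEC replicate 5 and up to 3215574 in WT replicate 9, which sets the precision for messenger RNA. The repeat genes Rn7s1 and Rn7s2 had counts within 0.0441% of each other in every library, so reads with several positions appear to have been counted at each. Values of close paralogs (the H2-Q and H2-T genes, guanylate-binding proteins, Tgtp1 and Tgtp2, the Reg3 and alpha-defensin families, Mt1 and Mt2) are therefore uncertain, as are those of overlapping and antisense genes. As a check for a library deposited more than once, counts were compared within each group, and no pair agreed within counting noise (chi-square per degree of freedom 10.7 to 72.4).

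Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 with the group, which left 15911, and libraries were scaled with TMM factors. The main test was edgeR's quasi-likelihood F test with robust dispersion estimates, dIEC against WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2, dIEC against WT. Their standard error is the size of the log2 fold change divided by the square root of F. CPM values are counts per 1000000 counts of the library, the library total being multiplied by its TMM factor. H2-Ab1, ratios of genes and library measures were also compared with two-sided exact permutation tests over all 462 splits of the libraries, whose smallest p is 0.00433. On counts simulated from these libraries over 15911 genes, the test for dIEC against WT recovered 82 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, with 13 false calls. The simulated genes varied independently and lacked any structure shared by the real libraries. These shares are therefore no measure of how many changes the test finds in the real counts.

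Before the data were examined, 42 lists of genes were fixed for cell types and processes of the ileum. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with the correlation estimated from each list, and fry, stand beside it. A list's score in a library is the mean log2 CPM of its members. Of 5 simulated sets of 20 genes shifted together, camera called 5, and of 20 unshifted sets it called 0. The simulated genes varied independently, while the correlation estimated within the real lists reached 0.906 (smooth muscle). The simulation therefore does not give the rate of false calls for the real lists. For 4 lists fewer than 5 members were measured and no test was made: follicular B cell (3 of 20 measured), neutrophil (0 of 17), mast cell and eosinophil (1 of 16) and pancreatic acinar (1 of 14). Also fixed beforehand was the rule for the genes named. It takes H2-Ab1 and every measured class II gene, up to 12 genes past the threshold in each direction with a mean of at least 1 CPM, the 6 genes with the lowest p in a direction with fewer than 3 calls, and up to 4 members with the lowest p from each list past its test. Predicted models and symbols of the Gm, Rik and clone kind were left out of the part on the threshold and the lowest p. No enrichment over Gene Ontology terms was planned.

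Alternatives covered the scaling (DESeq2 size factors, upper quartile, library size alone), the low-count filter (at least 1 count in any library, or a mean of at least 10), the test (DESeq2 1.42.0, limma-voom with sample quality weights, edgeR without robust estimates), each library left out, and covariates: the follicular B and smooth muscle lists and 1 surrogate variable from sva 3.50.0. An adjusted p under 0.1 and an added log2 fold change of at least 1 were tried as thresholds. After seeing the data, protein-coding genes alone without Lars2, the log2 ribosomal share as a covariate, and an exact permutation test of list scores were added. Results of 2 genes are not reported here.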

Results

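The 11 transcriptomes came from the distal ileum of mice given dextran sodium sulfate, 6 from WT mice and 5 from dIEC mice, in which Cre recombinase driven by the villin promoter acts on floxed H2-Ab1 in the intestinal epithelium. Total counts per library were 6603965 to 9681698, and protein-coding genes other than Lars2 held 22.9 to 37.3% of them. The single comparison, dIEC against WT, asks how the ileum's RNA differs between mice with and without this deletion of an MHC class II gene in the epithelium. Recombination and class II in the epithelial cells themselves were not measured. The piece was whole tissue, so each value mixes epithelium with immune cells, connective tissue and muscle wall. Libraries of the same group correlated at a Spearman rho across genes of 0.932 to 0.974 in WT and 0.927 to 0.973 in dIEC, and libraries of different groups at 0.914 to 0.972. The first principal component (34.1% of the variance) averaged -14.0 ± 24.8 (SD) in WT and 16.8 ± 23.1 in dIEC, a difference within the spread of the libraries (exact permutation p = 0.0779).

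H2-Ab1, the targeted gene, fell in the dIEC ileum to 0.313 of its WT level. It lies on chromosome 17 from 34257689 to 34269419 on the plus strand (GRCm38) and had 83.1 ± 27.4 CPM in WT (SD, n = 6) and 26.0 ± 9.87 CPM in dIEC (n = 5). Every dIEC library (16.8 to 39.2 CPM) lay below every WT library (47.5 to 112 CPM), and the two-sided exact permutation test of this gene gave the smallest p it allows, 0.00433. The log2 fold change was -1.68 with a standard error of 0.28 (95% interval -2.23 to -1.12). Adjusted over all genes by edgeR it did not pass, at adjusted p = 0.361, while DESeq2 gave an adjusted p of 4.17e-05. Over 25 settings its log2 fold change ran from -1.94 to -1.55 and its adjusted p from 4.17e-05 to 0.9998. Counts per gene do not show which exons the remaining reads cover.

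The other class II genes lay on the opposite side. H2-Aa, which encodes the alpha chain that pairs with the H2-Ab1 product, averaged 84.8 ± 22.2 CPM in WT and 145 ± 48.1 CPM in dIEC (exact permutation p = 0.0433). The ratio of H2-Ab1 to H2-Aa, which does not depend on how the libraries are scaled, was 1.01 ± 0.289 in WT and 0.199 ± 0.106 in dIEC, with no overlap between the groups (exact permutation p = 0.00433). Of the 9 measured genes of the class II list, which leaves H2-Ab1 out, 8 had log2 fold changes above 0, with a median of 0.60. Cd74, the invariant chain, had 233 CPM in WT and 388 in dIEC, H2-DMb1, a chain of the peptide exchange factor H2-DM, had 12.6 and 23.9, and Ciita, the transactivator of class II genes, had 17.3 and 26.3. Ifi30, a thiol reductase of the same pathway, had a log2 fold change of -0.01 ± 0.11 (SE). By edgeR 0 of the 9 passed over all genes (8 at an unadjusted p under 0.05, and H2-DMb1 by DESeq2) and 8 passed adjusted over the list alone. The list passed camera at adjusted p = 3.58e-07, and had an adjusted p = 0.472 with an estimated correlation.

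**Figure D1:**
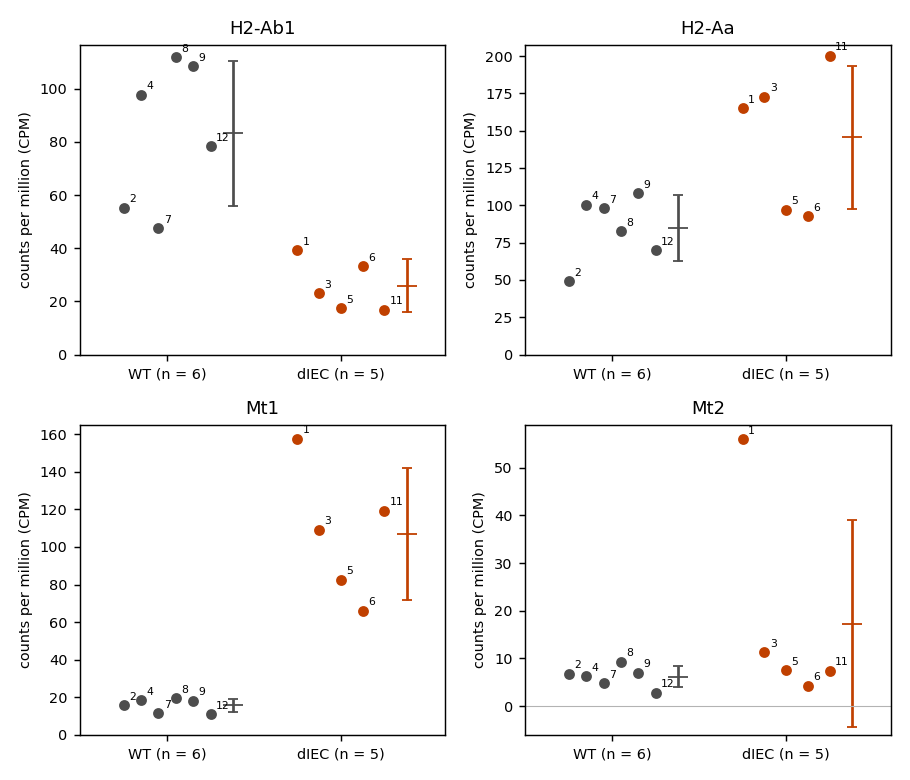
CPM of H2-Ab1, H2-Aa, Mt1 and Mt2 in each library, WT (6 libraries) and dIEC (5 libraries), each point numbered by its replicate, with bars for the mean ± SD. H2-Ab1 and Mt1 do not overlap between the groups, while Mt2 is at 55.9 CPM in dIEC replicate 1 and at most 11.3 CPM in the other libraries.

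Of the 15911 genes tested, 1 passed edgeR's adjusted threshold. Mt1, which encodes a metallothionein, a small protein that binds zinc and copper, rose 6.80-fold, from 15.7 ± 3.61 CPM in WT (SD, n = 6) to 107 ± 35.3 CPM in dIEC (n = 5). Its log2 fold change was 2.76 with a standard error of 0.22 (edgeR adjusted p = 0.000114), and the lowest dIEC library, at 66.0 CPM, was 3.41 times the highest WT library, at 19.4 CPM. Mt1 lies on chromosome 8 from 94179082 to 94180327 on the plus strand (GRCm38). The neighbouring and related metallothionein gene Mt2 (chromosome 8, 94172664 to 94173568) had 6.19 ± 2.18 CPM in WT and 17.3 ± 21.7 CPM in dIEC (exact permutation p = 0.199), and 55.9 CPM in dIEC replicate 1. The ratio of Mt1 to Mt2 was 2.70 ± 0.655 in WT and 10.97 ± 5.33 in dIEC (exact permutation p = 0.0130), with 2.82 in dIEC replicate 1.

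No gene passed edgeR's threshold as lower in dIEC (0 genes), and 921 lower and 775 higher genes had an unadjusted p under 0.05, which is 10.7% of those tested. DESeq2 called 9 genes higher and 2 lower. The higher ones were Mt1, 2210016F16Rik, H2-DMb1, Guca2b (uroguanylin, a peptide that controls intestinal fluid secretion), Ccl5 (a chemokine of cytotoxic lymphocytes), Zbp1 (a sensor of nucleic acids), Pfkfb3 (a regulator of glycolysis), Xbp1 (a transcription factor of the unfolded protein response) and Socs3 (a feedback inhibitor of cytokine signalling), and the lower ones were H2-Ab1 and Pbx3, a homeobox factor. In edgeR, 2210016F16Rik, which the rule for named genes leaves out for its symbol and which is named for its DESeq2 call, had a log2 fold change of 0.66 ± 0.13 (SE, adjusted p = 0.361). Guca2b had a log2 fold change of 1.40 ± 0.31 (SE), Ccl5 1.24 ± 0.25, Zbp1 1.44 ± 0.32, Socs1 1.41 ± 0.31, Xbp1 0.46 ± 0.11 and Pbx3 -0.83 ± 0.17, all at adjusted p = 0.427. Other genes with the lowest p toward lower values were Depdc1a at -1.57 ± 0.29 (adjusted p = 0.361), and Ccdc191, Abcc5 and Gstm2, a glutathione transferase, at -0.93 ± 0.20, -0.63 ± 0.14 and -0.96 ± 0.22 (adjusted p = 0.427 for each). Depdc1a averaged only 1.88 CPM in WT and 0.62 CPM in dIEC, so its value rests on few reads. The edgeR count moved with WT replicate 8. Without this library 319 genes passed, 213 higher and 106 lower, against 1 gene with each of the other 10 libraries left out in turn.

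Of the 38 lists tested, 23 passed camera, 17 toward higher and 6 toward lower values in dIEC. None of the 38 passed when camera estimated the correlation within each list (lowest adjusted p = 0.472, and 2 lists at an unadjusted p under 0.05), by fry (lowest adjusted p = 0.276, 5 lists unadjusted) or by exact permutation of the list scores (lowest adjusted p = 0.294, 4 lists unadjusted). With the smooth muscle score as a covariate 15 lists passed camera. The endothelial, neuronal, type I and III interferon, IgA, bile acid, proximal gut, fatty acid oxidation and circadian lists were then lost. So was the smooth muscle list, whose loss was fixed in advance because the covariate was its own score. With 1 surrogate variable 12 passed, and 8 of the 23 kept their call: MHC class I and II, interferon-gamma, T cell, intraepithelial lymphocyte, IgA, proliferation and unfolded protein response. That variable followed the absorptive enterocyte score over the libraries, so the loss of the enterocyte and fibroblast lists is no test of their cause. Of the members of the 38 lists DESeq2 called H2-DMb1, Ccl5, Zbp1 and Xbp1 and no other. The ribosomal share of the counts was 34.6 ± 6.91% in WT (SD, n = 6) and 40.5 ± 8.50% in dIEC (n = 5; exact permutation p = 0.216). The directions below are those of camera with the preset correlation. With library size alone as the scaling, the median of all genes moved to -0.22, and the medians of the unfolded protein response list and of the IgA, pIgR and plasma cell list then lay below 0.

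**Figure D2:**
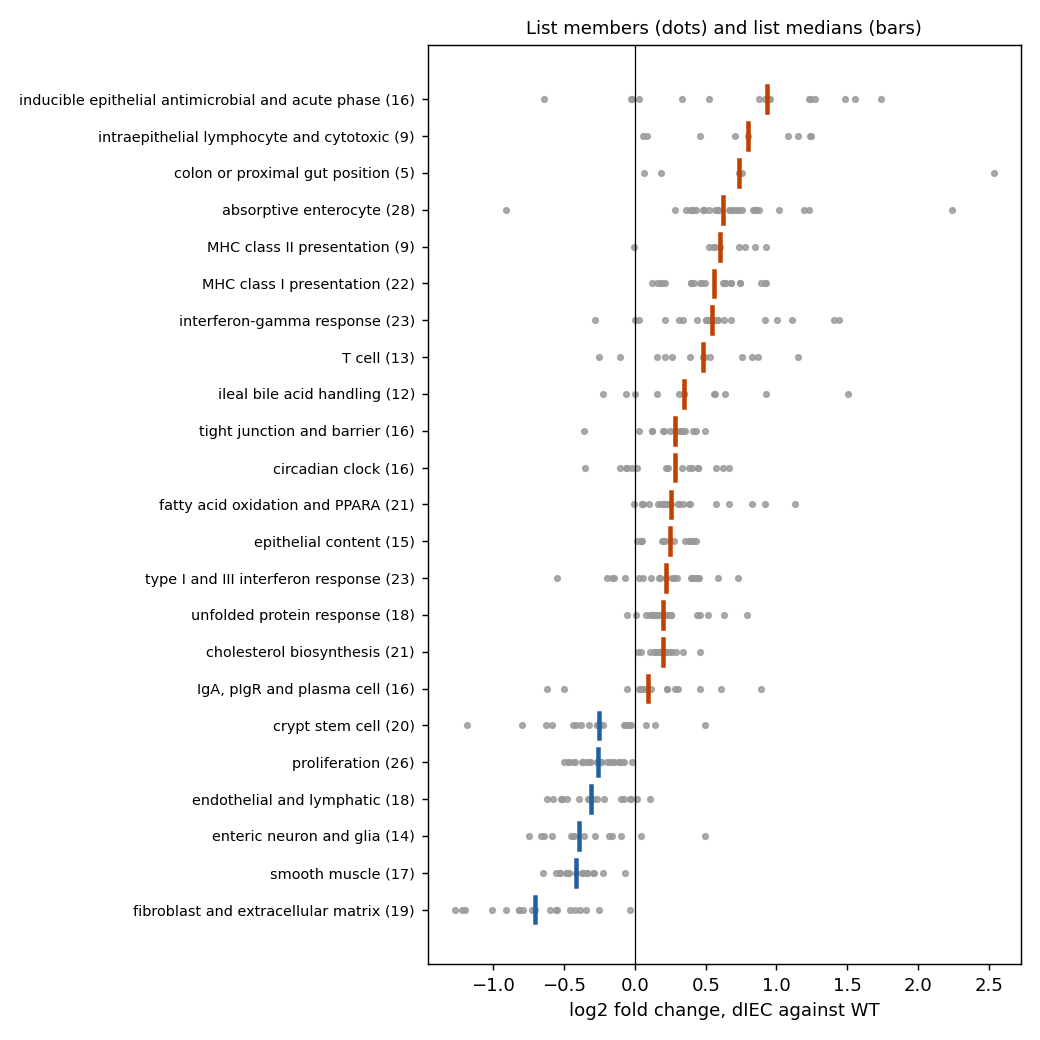
Log2 fold changes, dIEC against WT, of the measured members (grey dots) of the 23 lists past camera with the preset correlation, with the list medians as bars, orange for higher and blue for lower lists, and the number of members in parentheses. All 19 fibroblast and extracellular matrix genes lie below 0 and all 22 MHC class I genes above 0.

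Genes of MHC class I presentation lay higher in dIEC. All 22 had log2 fold changes above 0, with a median of 0.56. B2m, the light chain of class I molecules, had 150 CPM in WT and 240 in dIEC, Nlrc5, the class I transactivator, had 14.5 and 26.8, Psmb8, a subunit of the immunoproteasome, had 15.8 and 26.3, and H2-Q4, whose reads may be shared with its paralogs, had 19.0 and 31.8. Over all genes 0 passed edgeR (14 at an unadjusted p under 0.05), and 12 passed adjusted over the list alone. The list had an adjusted p = 8.75e-12 by camera and an adjusted p = 0.472 with an estimated correlation. Without TMM factors 18 of the 22 lay above 0.

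Interferon-gamma response genes lay on the same side, 22 of 23 above 0 with a median of 0.54. Zbp1 had 5.99 CPM in WT and 16.3 in dIEC, Socs1 0.912 and 2.45, the GTPase gene Igtp 5.51 and 11.8, and the transcription factor gene Irf8 36.6 and 51.8. By edgeR 0 passed over all genes (12 at an unadjusted p under 0.05, and Zbp1 by DESeq2), and 8 passed adjusted over the list alone. Camera gave an adjusted p = 5.87e-09, with an adjusted p = 0.472 with an estimated correlation. The scores were 2.91 ± 0.193 log2 CPM in WT and 3.40 ± 0.415 in dIEC (exact permutation p = 0.0433, adjusted p = 0.294), and 3 of the 5 dIEC libraries lay above the highest WT library. Type I and III interferon response genes had a smaller median of 0.22, with 18 of 23 above 0 and 0 past the threshold over all genes or adjusted over the list alone. Ifit1 among them had 4.60 ± 1.39 CPM in WT and 7.63 ± 4.02 in dIEC (SD), with 13.1 in dIEC replicate 11. That list passed camera at adjusted p = 0.0403 and had an adjusted p = 0.632 with an estimated correlation. Its camera call was lost without WT replicate 2, 8, 9 or 12 and without dIEC replicate 3 or 11, each left out alone, and its median was 0.11 without dIEC replicate 3 and 0.33 without dIEC replicate 5.

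Transcripts of intraepithelial and cytotoxic lymphocytes had the highest median among the immune cell lists. All 9 measured members of the 21 fixed for the list lay above 0, with a median of 0.80, and 4 of the 5 dIEC libraries scored above the highest WT library. Cd8a, a co-receptor chain of cytotoxic T cells, had 2.99 CPM in WT and 6.58 in dIEC, Cd7 had 1.64 and 3.83, Itgae, the alpha chain of the integrin CD103, had 6.65 and 11.5, and Ccl5 had 3.30 and 7.68. By edgeR 0 passed over all genes (6 at an unadjusted p under 0.05, and Ccl5 by DESeq2) and 6 passed adjusted over the list alone. The adjusted p by camera was 1.20e-06, and the adjusted p = 0.472 with an estimated correlation. The T cell list, which shares Cd8a, had 11 of 13 above 0 and a median of 0.48, with 0 past the threshold over all genes and 2, Cd3e and Cd8a, adjusted over the list alone (camera adjusted p = 0.000576, adjusted p = 0.472 with an estimated correlation), and without dIEC replicate 11 its median was 0.23. The IgA, pIgR and plasma cell list passed camera at adjusted p = 0.0386 with a median of 0.09, 0 genes past the threshold over all genes and 1, Xbp1, adjusted over the list alone, and had an adjusted p = 0.559 with an estimated correlation. That call was lost without WT replicate 4 or 8 and without dIEC replicate 1, 6 or 11, each left out alone. The follicular B, smooth muscle and ribosomal share covariates also removed it (camera adjusted p = 0.148, 0.231 and 0.0522). The median of the list was 0.028 without WT replicate 4 and -0.064 without dIEC replicate 6. It was 0.32, 0.15 and 0.16 without WT replicate 7, 9 or 12 and 0.27 and 0.23 without dIEC replicate 3 or 5. The CD4 T helper, dendritic cell, macrophage, innate lymphoid cell and inflammatory cytokine lists did not pass camera (adjusted p = 0.742, 0.2395, 0.274, 0.496 and 0.496). Of their members 9 of 24, 8 of 18, 16 of 21, 9 of 16 and 6 of 28 were measured. The other members were not tested, so these results do not cover them. In the dendritic cell list 2 genes, Itgae and Irf8, passed adjusted over the list alone.

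Absorptive enterocyte genes, those of the digestive and transport machinery of villus cells, lay higher in 27 of 28 cases with a median of 0.63. Sis, sucrase-isomaltase, had 295 ± 159 CPM in WT and 526 ± 171 in dIEC (SD), Slc2a5, a fructose transporter, 3.55 ± 1.75 and 8.20 ± 4.19, and Rbp2, a retinol-binding protein, 10.3 ± 7.10 and 23.4 ± 11.8. Apoa4, an apolipoprotein of chylomicrons, had 9.88 ± 11.4 and 46.1 ± 50.7, with 134 CPM in dIEC replicate 1 (at most 37.7 in the other dIEC libraries) and 32.5 in WT replicate 8 (at most 9.30 in the other WT libraries). No member passed over all genes or adjusted over the list alone (0 of 28 by edgeR, 5 at an unadjusted p under 0.05, and 0 by DESeq2). Camera gave an adjusted p = 9.97e-12, with an adjusted p = 0.472 with an estimated correlation. WT replicate 8 had the highest score of all libraries, 7.51 log2 CPM against 5.51 to 6.45 in the other WT libraries, and dIEC replicate 6 scored 6.03 against 6.90 to 7.25 in the other dIEC libraries. Without WT replicate 8 the median was 1.08 and 12 of the 28 genes passed over all genes, while with 1 surrogate variable the median was 0.019 and the list did not pass camera.

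Stromal transcripts lay on the lower side. All 19 genes of the fibroblast and extracellular matrix list were below 0, with a median of -0.71. Col1a1 and Col1a2, the chains of type I collagen, had 93.8 and 109 CPM in WT and 38.9 and 54.4 in dIEC, Lum, lumican, had 20.3 and 8.85, and Sparc, a matrix glycoprotein, had 47.5 and 27.1. By edgeR 0 passed over all genes (14 at an unadjusted p under 0.05) and 13 passed adjusted over the list alone. The camera adjusted p was 5.44e-08, with an adjusted p = 0.472 with an estimated correlation. WT replicate 8 scored 4.67 log2 CPM, below every dIEC library but replicate 1, and without it 3 genes of the list (Lum, Dpt and Pdgfra) passed over all genes. With 1 surrogate variable the median was -0.048 and the list did not pass camera. Smooth muscle genes were below 0 in 17 of 17 cases (median -0.41; Mylk, myosin light chain kinase, 522 and 379 CPM), enteric neuron and glia genes in 12 of 14 (median -0.39; Snap25, a synaptic protein, 5.80 and 3.504 CPM) and endothelial and lymphatic genes in 16 of 18 (median -0.31; Flt4, a growth factor receptor of lymphatic vessels, 9.19 and 6.01 CPM). In these 3 lists 0 genes passed over all genes or adjusted over the list alone. The smooth muscle median was -0.27 without WT replicate 4 and -0.26 without dIEC replicate 1. They passed camera at adjusted p = 2.74e-05, 0.00532 and 0.0164, and had adjusted p = 0.502, 0.482 and 0.618 with an estimated correlation. The endothelial call was lost without WT replicate 2 or 4 or dIEC replicate 3, each left out alone. It was also lost with the smooth muscle or the ribosomal share covariate. With 1 surrogate variable the endothelial list passed camera toward higher values (median difference in log2 CPM 0.12, adjusted p = 0.0475).

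**Figure D3:**
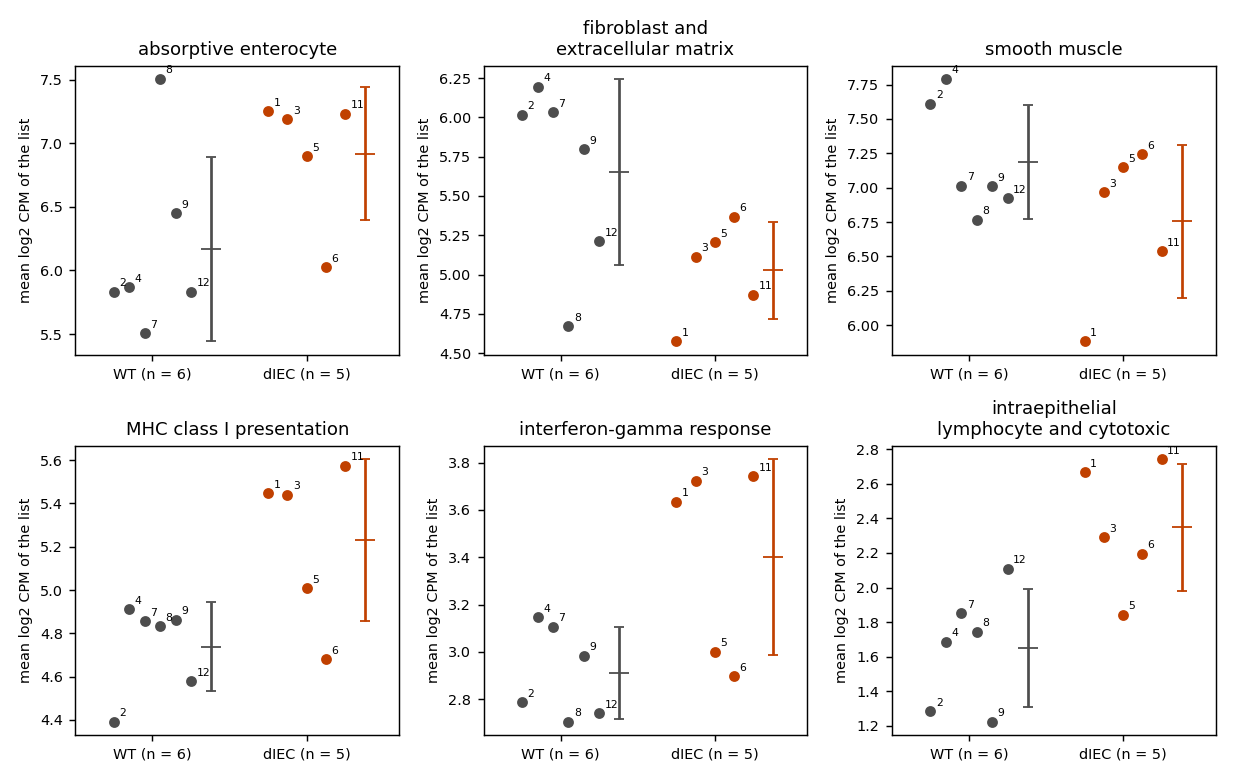
Mean log2 CPM of 6 lists in each library, WT (6 libraries) and dIEC (5 libraries), each point numbered by its replicate, with bars for the mean ± SD. WT replicate 8 lies above every dIEC library in the enterocyte list, among the dIEC libraries in the fibroblast list and at the low end of the WT libraries in the interferon-gamma list, and dIEC replicate 1 has the lowest smooth muscle score, 5.88.

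Other epithelial lists also passed camera. All 15 epithelial content genes (median 0.24), 15 of 16 tight junction genes (median 0.29), 9 of 12 genes of ileal bile acid handling (median 0.35) and 5 of 5 measured markers of colon or proximal gut (median 0.74) lay above 0, and 13 of 16 inducible antimicrobial and acute phase genes did so (median 0.93). Of the colon or proximal gut list only 5 of the 17 fixed genes were measured. That list mixes markers of both positions, so it does not show a shift in position. Slc51b, a chain of the basolateral bile acid exporter, had 25.4 ± 13.6 CPM in WT and 48.2 ± 17.9 in dIEC (SD), Lypd8, a secreted protein that binds flagellated bacteria, had 527 ± 136 and 967 ± 546, with 1832 and 1155 CPM in dIEC replicates 1 and 11 and at most 718 in the other dIEC libraries, and Reg3b, an antimicrobial lectin, had 1837 ± 1490 and 4302 ± 2701. Several of these values leaned on dIEC replicate 1. B3galt5, a galactosyltransferase on the colon or proximal gut list, had 80.6 CPM there and at most 6.01 in the other dIEC libraries. Without that library the median was 0.45 for colon or proximal gut and 0.49 for the antimicrobial genes, and both lists kept their camera call. With 1 surrogate variable neither list passed camera (median differences in log2 CPM 0.095 and 0.165, adjusted p = 0.842 and 0.256). The epithelial content median was 0.38 without WT replicate 8. The proliferation list lay lower, 26 of 26 below 0 with a median of -0.26, and so did 17 of 20 crypt stem cell genes (median -0.26; Tnfrsf19 6.83 and 3.998 CPM). For proliferation, dIEC replicates 1 and 5 scored 2.24 and 2.39 log2 CPM against 3.18 to 3.56 in the other dIEC libraries and 3.10 to 3.51 in WT, and the list median was -0.12, -0.16 and -0.43 without dIEC replicate 1, 5 or 6. The crypt stem cell median was -0.17 without dIEC replicate 1, and with 1 surrogate variable that list did not pass camera (adjusted p = 0.817). These 7 lists passed camera at adjusted p from 1.32e-05 to 0.00611. In none of them did a gene pass over all genes or adjusted over the list alone (0 by edgeR). With an estimated correlation the adjusted p = 0.482 for epithelial content and bile acid handling, 0.502 for proliferation and 0.472 for the other 4.

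Genes of fatty acid oxidation lay above 0 in 20 of 21 cases (median 0.26; Acadl, an acyl-CoA dehydrogenase, 31.1 and 55.3 CPM), cholesterol biosynthesis in 21 of 21 (median 0.20; Sqle, squalene epoxidase, 44.2 and 60.7), the unfolded protein response in 17 of 18 (median 0.20; Xbp1, 65.4 ± 6.87 and 89.8) and the circadian clock in 11 of 16 (median 0.28; Per2, 15.6 and 20.5). All 4 lists passed camera, with adjusted p = 0.000158, 0.000576, 0.000753 and 0.0315, and had adjusted p = 0.495, 0.502, 0.472 and 0.502 with an estimated correlation. By edgeR 0 of their genes passed over all genes, and Xbp1 and Dnajb11, both in the unfolded protein response list, passed adjusted over the list alone. The circadian call was lost without WT replicate 9 or 12 or dIEC replicate 1, each left out alone, and its median was 0.17 without WT replicate 9 and 0.065 without dIEC replicate 1. That call was also lost with the follicular B covariate (camera adjusted p = 0.0576). Arntl, another clock gene of the list, lay lower at a log2 fold change of -0.35 ± 0.13 (SE), and 5 of the 16 members were below 0. The median of this list therefore gives no common direction of the clock genes. The fatty acid oxidation median was 0.12 without dIEC replicate 1, and the cholesterol median was 0.30 without WT replicate 8 and 0.12 without dIEC replicate 3. The lists for Paneth cells (adjusted p = 0.2395), goblet cells (0.867), enteroendocrine cells (0.498), tuft cells (0.828), oxidative phosphorylation (0.165), mitochondrially encoded genes (0.498), xenobiotic response (0.885), immediate early genes (0.132), adipocytes (0.999) and erythrocytes (0.670) did not pass camera. Median log2 fold changes were 0.06 for the 21 Paneth cell genes and -0.05 for the 21 goblet cell genes, and list scores of both were within the spread of the libraries (exact permutation p = 0.758 and 0.719). By that test only 4 of the 38 lists had an unadjusted p under 0.05, so most lists past camera also lay within this spread.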

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

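All samples far from the rest of their group were looked for with a test fixed beforehand, and no test in this part was chosen after its result was seen. Dixon's test compares the gap between the highest or lowest library and its nearest neighbour with the whole range of the group, at the 95% critical value for its number of libraries. It was made on the CPM of 102 genes, the scores of 38 lists and 2 measures of the libraries, in each group, which is 284 tests. It singled out a library in 19 of them, where chance alone, at about 1 in 20, would give 14.2. Genes and lists that share members or cell types are not independent, and the 19 results gathered in few libraries: 7 in WT replicate 8 and 7 in dIEC replicate 1.

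WT replicate 8 was the highest WT library for 7 genes. Those of enterocytes and the epithelium were Sis (600 CPM, next library 321 CPM, ratio 0.639), Rbp2 (24.0 and 11.6 CPM, ratio 0.640), Apoa4 (32.5 and 9.30 CPM, ratio 0.755), Cldn7, a claudin (212 and 131 CPM, ratio 0.693) and Slc51a, a bile acid exporter chain (162 and 95.1 CPM, ratio 0.630). Those of lipid metabolism were Vnn1 (38.8 and 18.9 CPM, ratio 0.677) and Msmo1 (54.8 and 32.7 CPM, ratio 0.707). Total count and ribosomal share did not set this library apart.

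dIEC replicate 1 was the highest dIEC library for 6 genes and 1 list. B3galt5, a galactosyltransferase, had 80.6 CPM there and at most 6.01 CPM in the other dIEC libraries (ratio 0.952). Ighm, the heavy chain of immunoglobulin M, had 28.9 and 4.91 CPM (ratio 0.872), Herpud1 72.7 and 37.4 CPM (ratio 0.806), Apoa4 134 and 37.7 CPM (ratio 0.7455), H2-DMb2 4.19 and 3.04 CPM (ratio 0.747) and Nr1h4, the bile acid receptor FXR, 126 and 83.3 CPM (ratio 0.722). The list for colon or proximal gut position scored 5.72 log2 CPM and at most 4.60 in the others (ratio 0.817), and its camera call held without this library.

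The remaining 5 results were spread over other libraries. WT replicate 2 was the lowest WT library for H2-DMa (6.53 CPM, next 10.6 CPM, ratio 0.675) and Cd74 (135 and 226 CPM, ratio 0.692). dIEC replicate 5 was the highest for Marveld3 (29.9 and 25.8 CPM, ratio 0.808). dIEC replicate 6 had the lowest enterocyte score (6.03 and 6.90 log2 CPM, ratio 0.712), and WT replicate 9 the highest score for immediate early and heat shock genes (3.37 and 2.89 log2 CPM, ratio 0.716).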

How the results depend on the processing

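Protein-coding genes alone, the ribosomal share covariate and the exact permutation of list scores were chosen after seeing the data. The number of genes past edgeR's threshold was 1 in most settings. It was 2 (1 higher, 1 lower) with library size alone and 11 (9 higher, 2 lower) with DESeq2. With 1 library left out it ran from 1 to 319 (1 to 213 higher, 0 to 106 lower), and the 319 came without WT replicate 8. H2-Ab1 stayed lower in every setting. It passed the threshold over all genes with library size alone (-1.90), with DESeq2 (-1.67) and without WT replicate 8 (-1.57), and with 1 library left out it ran from -1.87 to -1.55. The number of lists past camera was 15 with the smooth muscle covariate, 12 with 1 surrogate variable, 0 with an estimated correlation, 0 by fry and 0 by exact permutation, and 21 to 25 with 1 library left out. In each case the cause was not tested. Of the 23 lists, 19 kept their camera call in every fit with a library left out.

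Over the named genes 2462 values under alternatives were compared with those reported: 2417 kept direction and side of the threshold, 29 passed it, and 16 changed sign. Ifi30, near 0 throughout, was above 0 without a low-count filter, with the follicular B covariate and with the ribosomal share covariate (0.00142, 0.00150 and 0.00347), and ran from -0.074 to 0.053 with 1 library left out. With the surrogate variable Cldn7 was at -0.0100, Lgals4 at -0.0082, Pigr at -0.036 and Ccl21a at 0.031. With library size alone Srebf2 was at -0.0100 and Gata6 at -0.026. Ighm was at -0.50 with limma-voom, -0.27 with the smooth muscle covariate and ran from -0.60 (without dIEC replicate 1) to 1.17 with 1 library left out. Of 414 list values, 369 kept their call, 39 lost it, and 6 turned camera's direction, all with the surrogate variable, where the median log2 difference was 0.050 for smooth muscle, -0.023 for epithelial content, -0.0056 for ileal bile acid handling, -0.025 for enteric neuron and glia, 0.12 for endothelial and lymphatic and 0.017 for circadian clock. The medians of enteric neuron and glia and of circadian clock kept their sign there, while that of tight junction and barrier, whose camera direction held, was -0.011. The cause was not tested.

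The follicular B covariate rested on 3 measured genes. Sex could not be fitted, since all 11 libraries had 3913 to 7862 counts of Xist and at most 1 of Uty. No paired analysis was made because the labels give no pairing. The replicate numbers are library numbers and do not tell which mice shared a litter or cage. The libraries held 1510296 to 3215574 protein-coding counts. None of 17 neutrophil genes passed the low-count filter, which does not tell low depth from few neutrophils.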

Other observations

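Both tests of Mt1, the fits without WT replicate 8 by list and the ribosomal share test were chosen after the data were seen, though the ribosomal prediction was written before its result. The 319 genes that edgeR called without WT replicate 8 all had the same sign with every library included, and 211 of them had an unadjusted p under 0.05 there. Both fits share all the other libraries, so this agreement is no independent support for the calls. Among the 213 higher genes were 12 of the 28 absorptive enterocyte genes: Slc5a1, the sodium-glucose transporter (log2 fold change 1.31 ± 0.19 SE without this library, 0.74 with it), Dpp4, Sis, Krt20, Apoc3, Mgam, Ace, Anpep, Myo1a, Vil1, Apob and Cdhr5. Slc51a and Slc10a2, which carry bile acids out of and into the enterocyte, were higher too. Lum (-1.38 ± 0.20 and -1.20), Dpt (-0.89 ± 0.14 and -0.73) and Pdgfra of the fibroblast list and Flt4 of the endothelial list were among the 106 lower genes. H2-DMb1 of the class II list, Socs1 of the interferon-gamma list and Ccl5 of the intraepithelial lymphocyte list were among the higher genes. None of the 22 MHC class I genes was called without WT replicate 8 (0 by edgeR), nor was any of the 26 proliferation genes (0).

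Groups of the 11 libraries drawn at random put these counts in context. Of 100 splits into 6 and 5 libraries, the real one included, 5 gave at least the 1 gene of the real split, so chance cannot be excluded for that count, and the highest other split gave 2100 genes. The 2 splits with more than 100 genes both placed WT replicate 8 beside dIEC replicates 1, 3 and 11, which points to a structure of the samples that the groups do not follow. For lists, 2 of the 100 splits, the real one included, gave at least 23 (25 lists in the highest other split), which is under the bound of 0.05 set for excluding chance, though 100 draws give this share only roughly. The other splits had a median of 14 lists, so camera with the preset correlation calls many lists under random groupings too. In the real split 90 genes (0.566%) had groups that did not overlap, where chance gives 0.433%, and 9 of the 100 splits gave at least its 1696 genes at an unadjusted p under 0.05.

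Mt1 was higher in every dIEC library than in any WT library, and a signal that induces both metallothionein genes, such as metals or stress, would raise Mt2 with it. Over all libraries the log2 fold change was 1.49 ± 0.61 (SE) for Mt2 and 2.76 ± 0.22 for Mt1, and without dIEC replicate 1, on which the Mt2 value rests, it was 0.33 ± 0.30 and 2.58 ± 0.19. The ratio of Mt1 to Mt2 differed between the groups (exact permutation p = 0.0130), which argues against an equal induction of both as the whole cause, although in dIEC replicate 1 the ratio was within the WT range (2.82), so a joint induction stays open there. A candidate explanation is Mt1 sequence carried by the Cre transgene, since some Cre constructs end in a piece of the mouse Mt1 gene. The lowest dIEC library had 3.41 times the Mt1 of the highest WT library, which restates the pattern and decides nothing, and counts per gene do not show where on Mt1 the reads lie and the labels do not name the construct, so this and an effect of the genotype on Mt1 alone cannot be told apart.

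Enterocyte genes lay higher and fibroblast genes lower in dIEC, with a gap between the list medians of 1.33 on the log2 scale. Without dIEC replicate 1 the gap was 1.14, above 0.5 of its value (0.667) by 0.471, more than the jackknife error of 0.338, which argues against this library as the cause. With the smooth muscle score as a covariate the gap was 0.72, and with the ribosomal share as a covariate 1.09, with jackknife errors of 0.472 and 0.636 that cover the margins of 0.0541 and 0.427. With 1 surrogate variable, estimated from the same libraries, the gap was 0.066 (medians 0.019 and -0.048). That variable followed the enterocyte score. It was lowest in dIEC replicate 1 and WT replicate 8 (-0.54 and -0.37), where the score was highest (7.25 and 7.51 log2 CPM). It was highest in WT replicate 4 (0.40, score 5.87). Fitting it therefore takes out the pattern itself, and the small gap decides nothing on its cause. The share of muscle wall in the piece and the ribosomal content of the libraries therefore may account for some or all of this pattern. The spread over 11 libraries is too wide to decide this. For muscle wall, more libraries would not decide it either. The smooth muscle score comes from the same mixed tissue, and a larger share of mucosa from any cause would lower it. This covariate therefore cannot tell the share of muscle wall from an effect of the genotype on the mucosa. Such an effect stays open and was not tested.

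The antigen presentation, interferon-gamma and intraepithelial lymphocyte lists lay higher in dIEC, with a median over their 63 measured genes of 0.57. The median was 0.71 with the ribosomal share as a covariate, 0.54 without dIEC replicate 1 and 0.44 with the smooth muscle score as a covariate, and 0.45 with 1 surrogate variable. The first 3 stayed above 0.5 of the reported value (0.285) by more than its jackknife error (0.146, 0.146 and 0.140), which argues against each as the whole cause. What stays open includes the number and kind of immune cells in the piece and the genotype itself. Cage, litter and batch, which are not given in the sources used here, stay open too. The Cre transgene, carried by the dIEC mice alone, cannot be told apart from the deletion. No list passed with an estimated correlation, and dIEC replicates 5 and 6 scored within the WT range for interferon-gamma genes (3.001 and 2.897 log2 CPM, WT 2.70 to 3.15).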
